A study of Homo sapiens with 6 samples.

How the data were processed

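RNA of 6 samples was sequenced, in 3 groups of 2: undifferentiated human iPSC, cardiomyocytes purified with antibodies and cardiomyocytes purified with a microRNA switch. Per the labels, libraries were made with a stranded total RNA kit with removal of ribosomal RNA. Per the submitters' processing notes, the tools were bcl2fastq 2.17.14, cutadapt 1.15, Bowtie2 2.2.5, STAR 2.5.3a, HTSeq 0.9.1, R 3.4.3 and DESeq2 1.18.1, with the genome build GRCh38. Their roles, the annotation release and the strand setting of the counting are not given.

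The deposited signal values are read counts per gene divided by a size factor per library. In each column every value was a whole multiple of a single step. Dividing by it gave whole reads for 100% of values within 0.001 of a read, with a largest distance of 4.84e-05. The inverse of the step equalled the median-of-ratios size factor of the recovered reads, with a largest difference of 3.27e-12. In 2 columns, 1 in each cardiomyocyte group, the step lies so close to 1 that a generic check for whole reads does not score them, and their reads rest on the multiples alone. The table lists 32306 genes, none with fewer than 2 reads in total. Names of 27 rows had been turned into dates, and these genes are not named. Of the names 97.4% matched GENCODE release 29, which gave the locations by symbol.

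The recovered reads numbered 17705851 and 17685930 in the iPSC, 19586922 and 19911448 in the antibody-purified and 18710748 and 19680362 in the switch-purified libraries. The floor for a gene with 0 reads in a group was 3 reads per library, a normalized value of 2.88 to 3.11. Ratios that rest on 1 to 3 reads have 95% binomial intervals. Floors and intervals cover counting error only, since copies made by PCR cannot be told apart.

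Groups were taken from the sample titles. 1 switch-purified column carries a number that no title has, so it was used as a library of that group without a number of its own. Nothing in the labels says that the libraries of a group came from separate cultures. Chi-square per degree of freedom, over genes with at least 20 reads, was 1.91 between the iPSC, 19.2 between the antibody-purified and 13.3 between the switch-purified libraries, where sampling alone gives 1. Between an antibody-purified and a switch-purified library it ran from 5.43 to 24.9, so some libraries of different methods were closer than those of the same method. The closest were SIRPA_0605 and switch_0605 (5.43), whose titles share a number, and then SIRPA_0619 and the switch-purified library whose number matches no title (9.29). The latter was at 11.4 against SIRPA_0605, and switch_0605 at 24.9 against SIRPA_0619.

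The design, the 24 gene lists, the naming rule and the alternatives not called added were fixed before the data were examined. Genes with a value of at least 10 in at least 2 libraries were tested, 19299 in all. The test was limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend) on log2(value + 1), with a coefficient per group over all 6 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01. They were adjusted over the lists of a comparison, and tested again with an estimated correlation and with fry. With the estimate, camera is also limited to the few residual degrees of freedom of the 6 libraries. Its adjusted p can therefore rise even where the estimated correlation is below the preset, as for pluripotency genes (-0.00165). The lists covered pluripotency, the sarcomere, calcium handling and ion channels, cardiac transcription factors, ventricular, atrial and nodal markers, energy metabolism, endothelial, mural, stromal, epicardial, endoderm, neural and blood cell markers, the purification antigens, proliferation, interferon, stress, p53, ATF4, hypoxia and cholesterol genes and mitochondrially encoded genes. After the data had been examined, a second endoderm list of 27 genes and an epithelial list of 15 genes were added.

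Genes were named by rule. Per comparison these were the 8 largest rises and falls by log2 fold change among genes past the threshold that changed at least 2-fold, had a mean of at least 100 in the higher group, did not overlap between groups and carried a gene symbol. Where none passed, the 5 with the smallest p in each direction were taken, as values, among genes with a symbol and a mean of at least 100 in the higher group. Per list, up to 4 members past the threshold with the smallest adjusted p were eligible, or else the 2 with the highest mean. The purification antigens and MYH6 and MYH7, which host miR-208a and miR-208b, were taken in every group.

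The alternatives were pseudocounts of 0.1 and 10, no filter, a filter at 100, upper-quartile rescaling, edgeR 4.0.16 on the recovered reads with TMM or with the deposited size factors, DESeq2 1.42.0, limma without a trend or on only the groups compared, a minimum fold change, each library left out, and a block for the number in the titles. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, limma recovered 36% and 88% for switch-purified cells against iPSC, 26% and 74% for antibody-purified cells against iPSC, and 38% and 84% between the methods, and called 7, 7 and 16 unchanged genes. edgeR recovered 85%, 88% and 86% of the 2-fold changes. The counts were drawn with the spread that edgeR's trend gives at each mean, and only genes above a minimum mean were changed. They held no spread particular to a gene and no difference shared by libraries of the same number. The rates may therefore be too high for the deposited libraries, and they do not show that differences missed there are absent. Reads shared by similar genes, such as MYH6 and MYH7 or HSPA1A and HSPA1B, may have been divided or dropped in counting, so these levels are uncertain in that respect. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.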

Results

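Gene expression was measured by RNA sequencing in undifferentiated cells of 201B7, an established human induced pluripotent stem cell (iPSC) line, and in cardiomyocytes differentiated from iPSC and purified in 2 ways. Each of the 3 groups had 2 libraries, with 17685930 to 19911448 reads assigned to genes per library. Switch-purified cells received, on day 17 of differentiation, an mRNA encoding CD4 that is controlled by miR-208a, a microRNA encoded in an intron of the cardiac myosin gene MYH6, and an mRNA for puromycin resistance. Cells displaying CD4 were removed with magnetic beads after 24 hours, and the remaining cells were kept in puromycin for 48 hours. Antibody-purified cells were sorted on day 20 as positive for SIRPA or SIRPB1 and negative for PECAM1, ITGA1, THY1 and PDGFRB. Values are normalized read counts, given as mean ± SD of 2 libraries. Adjusted p-values of genes are from limma and those of gene lists from camera, unless another tool is named, and log2 fold changes are on the scale of log2(value + 1).

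The first comparison asked how switch-purified cardiomyocytes differed from undifferentiated iPSC. TNNT2, which encodes cardiac troponin T (chromosome 1, 201359008 to 201377762, GRCh38), was at 54735 ± 470.4 against 136 ± 10.3 in iPSC, 402-fold higher (log2 fold change 8.64, SE 0.08, adjusted p = 1.34e-08). MYH6, the alpha myosin heavy chain gene (chromosome 14, 23381990 to 23408277), rose from 368 ± 111 to 819478 ± 27362 (log2 fold change 11.15, SE 0.20, adjusted p = 1.11e-07). SOX2, a core pluripotency factor (chromosome 3, 181711924 to 181714436), was at 3616 ± 131 in iPSC and had 0 reads in both switch-purified libraries, at least 1188-fold lower (adjusted p = 3.15e-07).

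All 22 tested sarcomere genes rose in switch-purified cells, and all did so when adjusted over the list alone. The list had a median log2 fold change of 8.89, or 8.63 with genes of 0 reads in iPSC at their bound (adjusted p = 1.49e-12, and 0.223 with an estimated correlation). TNNI1, the troponin I of fetal heart, rose from 14.5 ± 2.64 to 29157 ± 1614, TNNC1 reached 18505 ± 625 and NEBL 48582 ± 382. The largest rise among genes meeting the naming rule was that of MYH7, the beta myosin heavy chain gene (chromosome 14, 23412738 to 23435718), from 3.37 ± 0.662 to 31203.1 ± 12220 (log2 fold change 12.75, SE 0.39, adjusted p = 7.32e-07). CORIN, which encodes a protease that activates natriuretic peptides, reached 16797 ± 4219.8. LMOD2, an actin nucleator of the sarcomere, reached 3696 ± 1029 against 2 reads in iPSC, a ratio of 3817 with a counting interval of 1056 to 31526. RXRG (ratio 3105, counting interval 862 to 25742), GUCY1A3 at 5866 ± 436 and TECRL at 11124 ± 502 completed the 8 largest rises.

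All 14 cardiac transcription factors rose, and all did so when adjusted over the list alone (median log2 fold change 7.94, adjusted p = 3.04e-07). NKX2-5 (chromosome 5, 173232109 to 173235357) rose from 7.71 ± 0.0455 to 7051 ± 406, and TBX20 from 4.34 ± 0.708 to 6817 ± 427. Of 17 genes of calcium handling and ion channels 15 rose and 2 fell (adjusted p = 2.81e-06). PLN, which encodes phospholamban, the regulator of the sarcoplasmic calcium pump (chromosome 6, 118548298 to 118560730), had the smallest adjusted p of all tested genes, 4.3e-09, and rose from 16.4 ± 0.0968 to 23870 ± 514. Of 17 genes of fatty acid oxidation and energy metabolism 16 rose and 1 fell (adjusted p = 3.04e-07). CKM, muscle creatine kinase, rose from 16.9 ± 2.15 to 18853 ± 999, and COX6A2, a muscle subunit of cytochrome oxidase, was at 1046 ± 9.31 against 0 reads in iPSC, at least 362-fold higher. With an estimated correlation the adjusted p of these 3 lists was 0.223. Adjusted over the list alone, the counts of every list were the same in this comparison.

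Markers of several cardiac subtypes rose together. All 6 ventricular markers rose (median log2 fold change 8.08, or 7.52 with bounds, adjusted p = 0.000288, and 0.316 with an estimated correlation), among them IRX4 at 3820.4 ± 89.1 against 22.2 ± 8.05. Of 9 atrial markers 7 rose and 2 fell (adjusted p = 0.0148), with MYL7 at 93164 ± 3101 and NPPA, atrial natriuretic peptide, at 45856 ± 5394. Of 8 nodal markers 6 rose and 1 fell (adjusted p = 0.00761), with HCN4, a pacemaker channel gene, at 3399 ± 229 against 234 ± 23.2. With an estimated correlation the adjusted p of the atrial and of the nodal list was 0.223. Of 13 mitochondrially encoded genes 10 rose and 3 did not pass (median log2 fold change 0.76, adjusted p = 0.00269, and 0.475 with an estimated correlation). All mitochondrially encoded genes together took only 0.305% and 0.335% of reads in the iPSC and 0.453% and 0.430% in the switch-purified libraries. Whether such reads were lost in mapping or counting cannot be told, so their levels are uncertain.

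All 18 pluripotency genes and all 21 proliferation genes fell in switch-purified cells. The pluripotency list had a median log2 fold change of -8.05, or -7.92 with bounds (adjusted p = 6.79e-08, and 0.192 with an estimated correlation). DNMT3B, a de novo DNA methyltransferase (chromosome 20, 32762385 to 32809356), fell from 53864 ± 824 to 399.7 ± 7.20, and L1TD1 from 15312 ± 182 to 25.7 ± 8.58. ESRG, LINC00678, PRDM14, LINC00599, IDO1 and SYT6 had 0 reads in both switch-purified libraries and were at least 1468-, 1398-, 1374-, 912-, 777- and 510.4-fold lower than in iPSC. ZSCAN10 had 2 reads there and was at 3339 ± 229 in iPSC. ESRG is annotated as a sense intronic transcript, so its count may hold reads of a host gene. Proliferation genes had a median log2 fold change of -1.83 (adjusted p = 4.02e-08, and 0.39 with an estimated correlation). MKI67 was at 1158 ± 31.9 against 4103 ± 148, and MCM6, a replication helicase subunit, at 768 ± 60.4 against 3842 ± 158.

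Markers of other cell types went in different directions. Of 11 endoderm and hepatic markers 10 rose and 1 did not pass (median log2 fold change 5.38, or 4.53 with bounds, adjusted p = 0.00396, and 0.531 with an estimated correlation). AFP, the alpha-fetoprotein gene of yolk sac and fetal liver (chromosome 4, 73431138 to 73456174), was at 2987 ± 1823 against 22.2 ± 5.32 (adjusted p = 0.000256), and ALB at 513 ± 480.1 against 0 reads, at least 177-fold higher (295-fold without switch_0605 and 60.1-fold without the other switch-purified library). All 6 neural markers fell (median -4.03, or -3.39 with bounds, adjusted p = 0.0208, and 0.235 with an estimated correlation), with OTX2 at 14.7 ± 3.16 against 818 ± 17.7. Of 12 smooth muscle and mural markers 8 rose and 2 fell (adjusted p = 0.0334, and 0.37 with an estimated correlation). LMOD1 rose to 1939 ± 55.8 and NOTCH3 fell to 411 ± 14.7. The endothelial list (5 rose, 5 fell), the fibroblast and stromal list (4 rose, 7 fell) and the epicardial list (1 rose, 1 fell) were not called, at adjusted p of 0.981, 0.578 and 0.697. ENG rose to 4486 ± 361, KDR fell to 472 ± 179 and COL1A1 fell to 408 ± 52.6. The endothelial list had a median of -0.22, a mean of 0.71 and an upward test, and the epicardial list a median of 0.75, a mean of -0.05 and an upward test. Of the blood cell markers 2 were tested, too few for a list test. CD34 fell to 5.55 ± 1.99 from 184 ± 6.42, and RUNX1 was lower (adjusted p = 0.0167), but not past the threshold without iPSC library 1 (0.0966), iPSC library 2 (0.147) or the switch-purified library whose number matches no title (0.0578), nor with no filter on low values (0.0534).

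Among stress and metabolic lists, 12 of 18 immediate early and dissociation stress genes rose, 1 fell and 5 did not pass (median log2 fold change 1.94, adjusted p = 0.0175, and 0.583 with an estimated correlation). Within the group these genes were higher in switch_0605 than in the other library, by a median log2 difference of 1.16. BTG2 rose to 2754 ± 567 from 230.0 ± 6.14. Of 12 cholesterol synthesis genes 9 fell and 1 rose (adjusted p = 0.0338, and 0.418 with an estimated correlation). The interferon (4 rose, 8 fell), p53 (1 rose, 8 fell), ATF4 and unfolded protein response (3 rose, 8 fell) and hypoxia and glycolysis lists (6 rose, 3 fell) were not called, at adjusted p of 0.431, 0.0677, 0.162 and 0.131. The p53 list would be called lower without the switch-purified library whose number matches no title (adjusted p = 0.0294). IFITM1 fell to 35.1 ± 4.59 from 4121 ± 73.4, and PHGDH, the first enzyme of serine synthesis, fell to 887 ± 152 from 9108 ± 54.4.

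In all, limma called 14667 of 19299 genes between switch-purified cells and iPSC, 7015 higher and 7652 lower, of which 4411 and 5225 changed at least 2-fold. Of 23 lists tested 15 were called, 0 with an estimated correlation and 21 by fry.

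**Figure D1:**
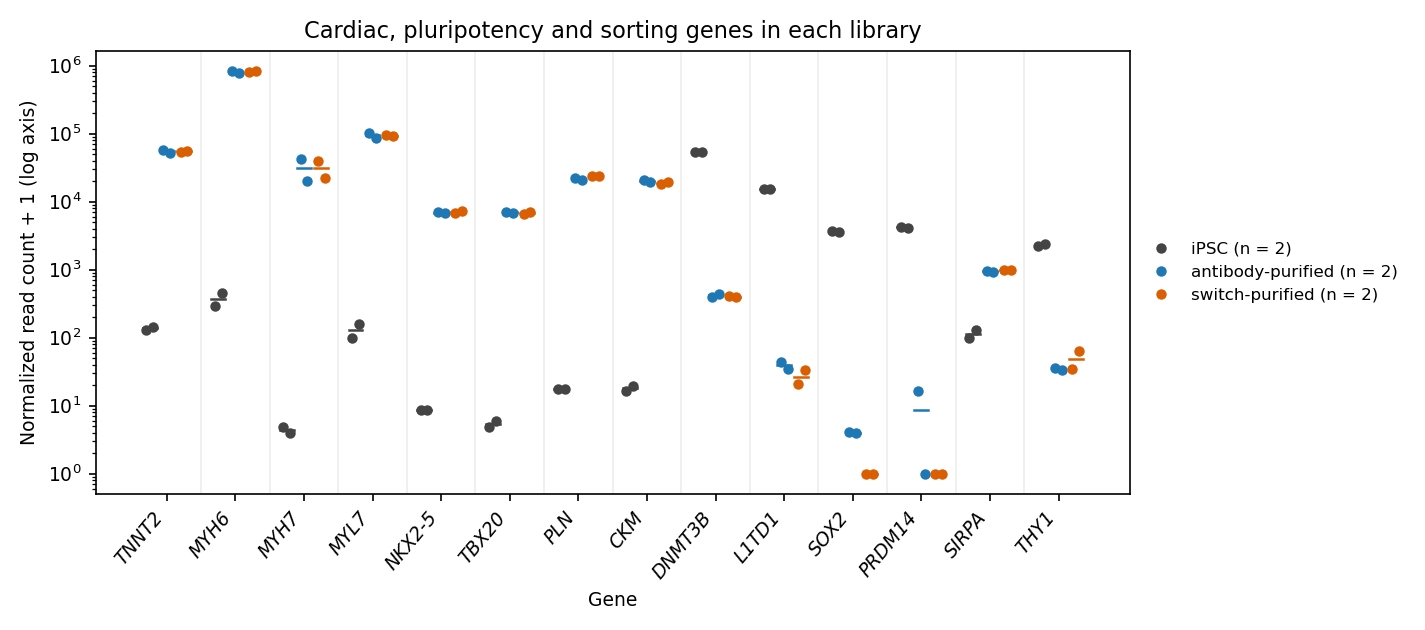
Normalized read count + 1 on a log axis for marker genes in each of the 6 libraries, with points for libraries and bars for the mean of each group of 2. TNNT2 lies at 136 in iPSC, 54735.1 in switch-purified and 55060.5 in antibody-purified cells, and SOX2 at 3616, 0 and 2.97.

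The same question was asked of antibody-purified cardiomyocytes. TNNT2 was at 55060.5 ± 4472, 405-fold above iPSC (log2 fold change 8.65, SE 0.08, adjusted p = 1.33e-08), and MYH6 at 809186 ± 28541 (log2 fold change 11.13, SE 0.20, adjusted p = 1.1e-07). Across the 4 cardiomyocyte libraries MYH6 took 4.08% to 4.29% of reads. DNMT3B fell to 418 ± 26.9 (log2 fold change -7.01, SE 0.07, adjusted p = 1.33e-08). SERPINA1, the alpha-1-antitrypsin gene of liver (chromosome 14, 94376747 to 94390693), reached 3012 ± 2079 against 1 read in iPSC, a ratio of 6220.0 with a counting interval of 1131 to 249096, among the 8 largest rises. The ratio depended on the library, since SERPINA1 was at 1542 in SIRPA_0605 and 4482 in SIRPA_0619.

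All 22 sarcomere genes rose in antibody-purified cells (median log2 fold change 8.83, or 8.64 with bounds, adjusted p = 1.11e-12), with TNNI1 at 30209 ± 2065 and NEBL at 45346 ± 1423. All 14 cardiac transcription factors rose (adjusted p = 2.71e-07), with NKX2-5 at 6905 ± 55.6 and TBX20 at 6949 ± 257. Of 17 calcium handling and ion channel genes 15 rose and 2 fell (adjusted p = 2.88e-06), with PLN at 21412 ± 836. Of 17 energy metabolism genes 16 rose and 1 fell (adjusted p = 2.71e-07), with CKM at 20032 ± 1124. Of 9 atrial markers 7 rose and 2 fell (adjusted p = 0.0101), and of 8 nodal markers 6 rose and 1 fell (adjusted p = 0.00899). With an estimated correlation the adjusted p of these 6 lists was 0.205. All 6 ventricular markers rose (median log2 fold change 7.48 with bounds, adjusted p = 0.000275, and 0.315 with an estimated correlation), and 9 of 13 mitochondrially encoded genes rose (adjusted p = 0.00233, and 0.461 with an estimated correlation). These counts were the same when adjusted over the list alone. MYH7 at 31176 ± 15947, CORIN at 16654 ± 5336 and GUCY1A3 at 5729.7 ± 651 were also among the 8 largest rises, as were LMOD2 and RXRG, which had 2 and 2 reads in iPSC.

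All 18 pluripotency genes fell in antibody-purified cells (median log2 fold change -8.21, or -7.89 with bounds, adjusted p = 6.58e-08, and 0.192 with an estimated correlation), and so did all 21 proliferation genes (median -1.86, adjusted p = 3.08e-08, and 0.385 with an estimated correlation). SOX2 was at 2.97 ± 0.0819, POU5F1, which encodes OCT4, at 29.6 ± 28.1 against 19061 ± 22.5 in iPSC, and MKI67 at 1237 ± 80.3. LINC00678 at 3.03 ± 4.28, PRDM14 at 7.57 ± 10.7, ESRG at 4.00 ± 2.91 and LINC00599 at 3.01 ± 2.88 were also among the 8 largest falls, as were IDO1 and KCNG3, with 3 and 2 reads. 

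All 11 endoderm and hepatic markers rose in antibody-purified cells, and all did so when adjusted over the list alone (median log2 fold change 8.12, or 7.67 with bounds, adjusted p = 0.00052, and 0.461 with an estimated correlation). AFP was at 17607 ± 17764 (log2 fold change 9.08, SE 0.81, adjusted p = 7.2e-05), and FGB, a fibrinogen chain gene of hepatocytes, at 1485 ± 1619 against 0 reads, at least 513-fold higher (909-fold without SIRPA_0605 and 118-fold without SIRPA_0619). All 6 neural markers fell (median -4.19, or -3.73 with bounds, adjusted p = 0.0195, and 0.23 with an estimated correlation). Of 12 smooth muscle and mural markers 8 rose and 2 fell (adjusted p = 0.0207, and 0.322 with an estimated correlation), and of 18 stress genes 13 rose and 1 fell (adjusted p = 0.00899, and 0.566 with an estimated correlation). Within the group the stress genes were higher in SIRPA_0605 than in SIRPA_0619, by a median log2 difference of 0.96. Of the blood cell markers 1 of 2 fell, and 2 when adjusted over the list alone.

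Not called in antibody-purified cells were the endothelial (5 rose, 5 fell), fibroblast and stromal (4 rose, 7 fell), epicardial (2 rose, 1 fell) and interferon lists (6 rose, 8 fell), at adjusted p of 0.838, 0.669, 0.506 and 0.655. Likewise not called were the p53 (1 rose, 8 fell), ATF4 and unfolded protein response (3 rose, 8 fell), hypoxia and glycolysis (6 rose, 2 fell) and cholesterol synthesis lists (1 rose, 9 fell), at 0.0802, 0.293, 0.0674 and 0.0648. Without the library SIRPA_0619 the p53 list would be called lower (0.047) and the hypoxia list higher (0.0314, and 0.0207 with no filter on low values). The endothelial list had a median of -0.41, a mean of 0.51 and a downward test, and the epicardial list a median of 0.50, a mean of -0.08 and an upward test. 

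In all, limma called 14587 genes between antibody-purified cells and iPSC, 7013 higher and 7574 lower, of which 4376 and 5138 changed at least 2-fold. Of 23 lists 14 were called, 0 with an estimated correlation and 21 by fry.

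**Figure D2:**
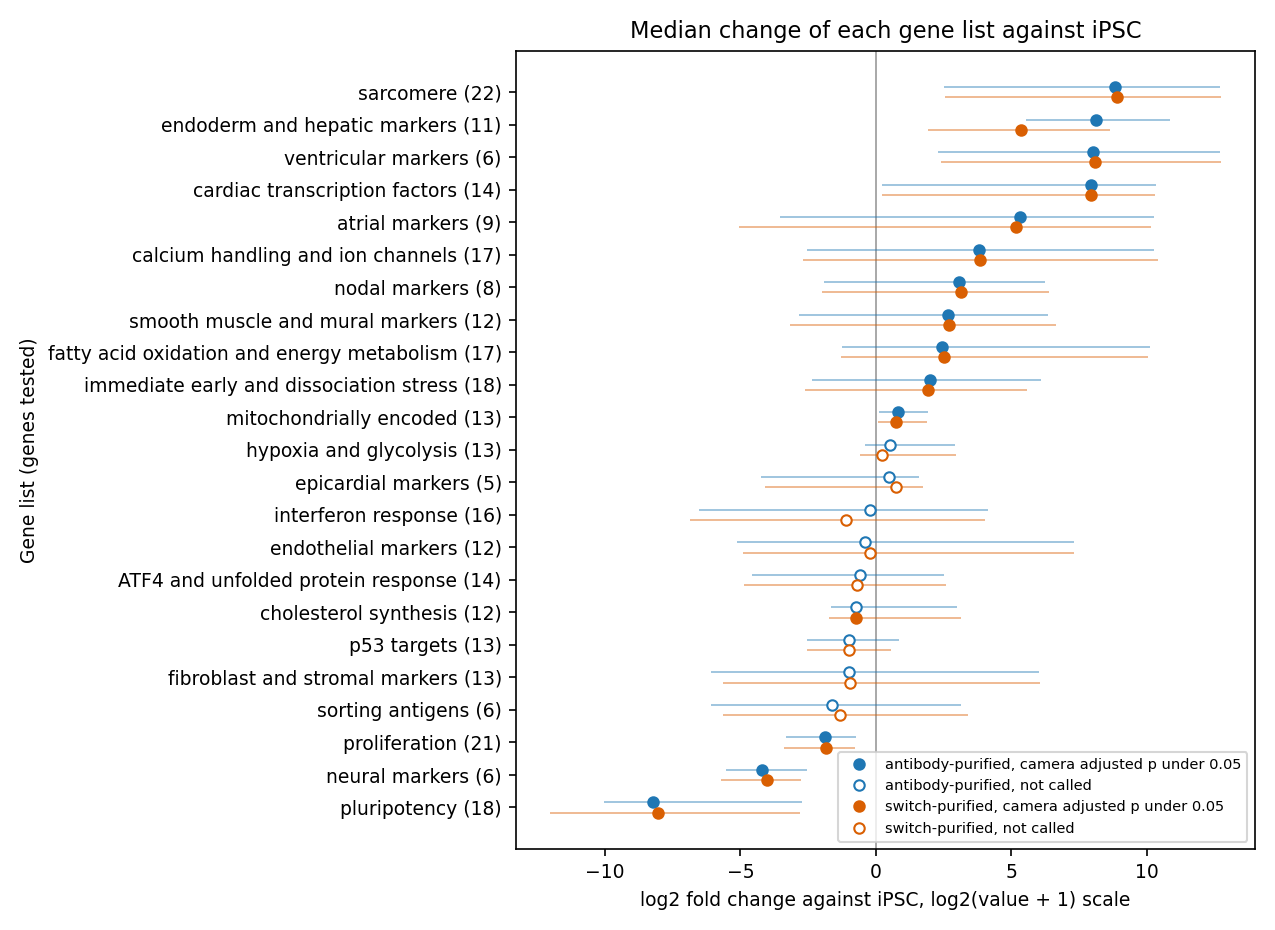
Log2 fold change against iPSC of each tested gene list in antibody-purified and switch-purified cells, with points at the median, lines from the lowest to the highest member and filled points where camera's adjusted p was under 0.05. Sarcomere genes lie at medians of 8.83 and 8.89, pluripotency genes at -8.21 and -8.05, and endoderm and hepatic markers at 8.12 and 5.38.

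The genes called in the purified groups against iPSC overlapped. In both comparisons 6706 genes were higher and 7217 lower, and 0 were called in opposite directions. Independent lists of these sizes would share 2549 and 3003. Simulated groups with no effect, set against shared simulated iPSC libraries, shared 0.04 and 0 on average over 50 simulations. Groups with no effect have almost no calls to share, so these counts cannot size the part due to shared controls. The log2 fold changes correlated at 0.983 across genes, which are not independent replicates, against 0.4997 in the simulations. Their covariance was 5.40 against 0.0522, the amount that shared controls alone gave in the simulations. The 2 iPSC libraries were not split between the comparisons, since each would have kept 1, so part of the overlap may come from shared controls.

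The third comparison set the purification methods against each other. Only switch-purified cells were transfected and kept in puromycin, so effects of these treatments on the cells and of the selection itself cannot be told apart. MYH6 was at 819478 ± 27362 in switch-purified and 809186 ± 28541 in antibody-purified cells (log2 difference 0.02, 95% interval -0.45 to 0.49), and MYH7 at 31203.1 ± 12220 and 31176 ± 15947 (log2 difference 0.04, 95% interval -0.89 to 0.98). The endoderm and hepatic list was lower in switch-purified cells, with a median log2 difference of -2.21 (adjusted p = 1.65e-09, and 0.68 with an estimated correlation). By limma none of its 11 members passed over all genes, and 9 were lower when adjusted over the list alone. DESeq2 called 1 member, SERPINA1, named after its values were seen, lower over all genes (log2 fold change -2.33, adjusted p = 0.000206). AFP was at 2987 ± 1823 in switch-purified and 17607 ± 17764 in antibody-purified cells (log2 difference -2.19, SE 0.81, adjusted p = 0.905), and APOB, the main apolipoprotein of lipoproteins made by liver, at 532 ± 302 and 4047 ± 4349.6 (log2 difference -2.43, SE 0.86, adjusted p = 0.871).

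For single genes limma called 0 of 19299, with a smallest adjusted p of 0.570. At an unadjusted p under 0.05 there were 978 genes, 226 higher and 752 lower in switch-purified cells, where chance gives 965, evenly split between the directions on average. The total was near this, but the lower genes outnumbered the higher ones. Genes are not independent, so the split was not tested. edgeR called 0 genes with TMM factors and 0 with the deposited size factors. A block for the number in the titles, which no label calls a batch, gave other counts. With it edgeR, in a fit added after seeing the data, called 342 genes, 28 higher and 314 lower. limma called 0 with the block, or 9 in all 6 libraries, a fit also added afterwards. DESeq2 without a block called 28, all lower in switch-purified cells. Without the library SIRPA_0605 limma called 41, also all lower. For 13281 genes (68.8%) the 95% interval of the difference lay within 2-fold in either direction, and for the others a 2-fold difference was not excluded. These intervals, like those of MYH6 and MYH7 above, rest on a spread shared by all 6 libraries, iPSC included. They do not measure the spread of the cardiomyocyte libraries alone. In a limma fit of only the 2 groups compared, 670 genes had an unadjusted p under 0.05.

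Since none passed, the genes with the smallest p among those with a gene symbol and a mean of at least 100 in the higher group, 5 in each direction, are given as values. Higher means in switch- than in antibody-purified cells were those of RB1 (1065 ± 4.09 and 887 ± 26.6), UBN2 (713 ± 22.7 and 595 ± 10.1), FTX (1562 ± 163 and 1233 ± 49.2), CSNK1G3 (656 ± 16.98 and 532 ± 40.6) and TRDMT1 (208 ± 7.63 and 154 ± 6.25), each at an adjusted p of 0.809. Lower means were those of KRT19, an epithelial keratin gene (2018 ± 81.0 and 3039.6 ± 412), CDH1, which encodes E-cadherin (41.0 ± 8.14 and 319.9 ± 224), CDH6 (14.7 ± 3.16 and 128 ± 86.7), CLDN6, a claudin gene (1284 ± 50.5 and 1649 ± 62.9), and C8orf4 (18.2 ± 6.65 and 101.3 ± 43.4), each at an adjusted p of 0.605. DESeq2 called these last 5 lower, at adjusted p of 0.0015, 0.00771, 0.000191, 0.0256 and 0.00754. Without the library SIRPA_0605 limma called CDH1 (0.0103) and CDH6 (0.0388) lower.

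**Figure D3:**
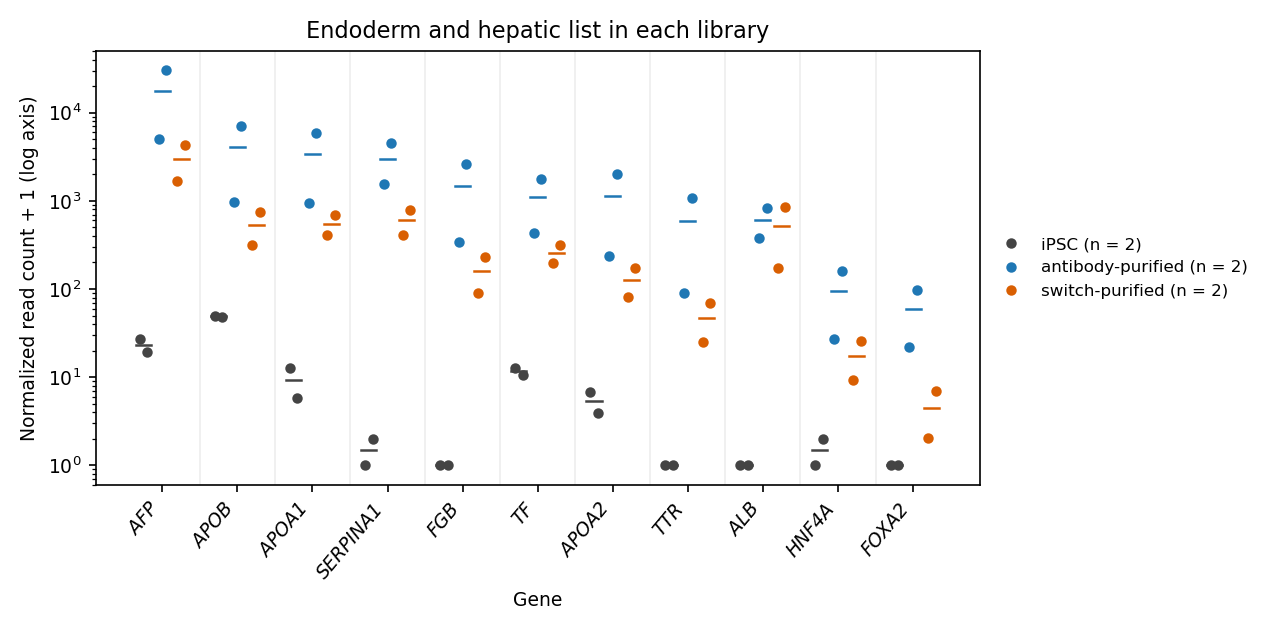
Normalized read count + 1 on a log axis for the tested endoderm and hepatic markers in each library, with points for libraries and bars for group means. AFP lies at 5046 and 30168 in the antibody-purified, 1698 and 4276 in the switch-purified and 25.9 and 18.4 in the iPSC libraries.

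Endoderm and hepatic markers also differed within the groups. All 11 were lower in SIRPA_0605 than in SIRPA_0619 and in switch_0605 than in the other switch-purified library, with median log2 differences of -2.58 and -1.33. Immediate early and dissociation stress genes went the other way, 15 of 18 being higher in both of these libraries, with medians of 0.96 and 1.16. With camera's preset correlation the endoderm list was called without any single library, at adjusted p from 5.89e-15 to 0.00117, but with all libraries adjusted p was 0.68 with an estimated correlation and 0.553 by fry, and the size of the difference depended on single libraries. Its median log2 difference was -3.49 without SIRPA_0605, -0.99 without SIRPA_0619, -1.80 without switch_0605 and -2.86 without the other switch-purified library. Between single libraries it was -1.57 for switch_0605 against SIRPA_0605 and -3.11 for the remaining libraries, which no label pairs. Of the 11 members, 10 were lower in the switch-purified library in both cases. ALB was lower in the first only (log2 differences -1.11 and 0.05). SIRPA_0605 and the other switch-purified library were near each other for AFP (5046 and 4276) and HNF4A (26.2 and 24.9). They lay further apart for SERPINA1 (1542 and 785) and FOXA2 (21.2 and 5.96), and ALB was higher in the switch-purified library (375 and 853). The other list called was that of ATF4 and unfolded protein response genes (median -0.15, adjusted p = 0.0322, and 0.68 with an estimated correlation), with 0 of 14 members passing over all genes or over the list alone. ATF4 was at 5047 ± 234 and 5642 ± 505 in switch- and antibody-purified cells. Its list was not called without iPSC library 1 (0.0539), iPSC library 2 (0.053), SIRPA_0619 (0.516) or switch_0605 (0.0993).

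No other list was called between the methods. Adjusted p was 0.475 for sarcomere, 0.311 for calcium handling, 0.452 for transcription factor, 0.808 for energy metabolism and 0.808 for mitochondrially encoded genes. It was 0.312 for ventricular, 0.312 for atrial and 0.107 for nodal markers, 0.0834 for pluripotency and 0.194 for proliferation genes. For endothelial, mural, stromal, epicardial and neural markers it was 0.222, 0.91, 0.866, 0.726 and 0.88, and for interferon, stress, p53, hypoxia and cholesterol genes 0.0834, 0.156, 0.476, 0.169 and 0.107. Over the list alone 1 pluripotency and 1 epicardial gene were lower. The pluripotency genes with the highest means were SALL4, at 1219.9 ± 51.7 and 1166 ± 188, and LIN28B, at 678 ± 88.8 and 712 ± 157 in switch- and antibody-purified cells. Median, mean and test differed in sign for sarcomere genes (-0.00, 0.03, upward), epicardial markers (0.14, 0.03, downward) and mitochondrially encoded genes (-0.01, -0.00, upward).

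List calls between the methods, all with camera's preset correlation, depended on single libraries. With all libraries and an estimated correlation the adjusted p of the lists named here was between 0.68 and 0.913, and the estimate was not made with libraries left out. Without SIRPA_0605 sarcomere (0.0125), interferon (0.0384) and cholesterol genes (0.0444) were called too, and without SIRPA_0619 stress (0.00507) and hypoxia genes (0.0238). Without switch_0605 the pluripotency (0.027), endothelial (0.00107), sorting antigen (0.0121), proliferation (0.0335) and stress lists (7.61e-09) were. Without the other switch-purified library the calcium handling (0.0447), nodal (0.0447), proliferation (6.33e-07), interferon (0.0239), stress (0.0233), p53 (0.0137) and cholesterol lists (0.0324) were. Each went in its direction with all libraries, except that proliferation genes without switch_0605 and stress genes without the other switch-purified library were called higher. With a pseudocount of 10 the interferon list was called as well (0.0307). The count of lists called, 2, became 1 without either iPSC library, 5 without SIRPA_0605, 6 without switch_0605 and 9 without the other switch-purified library.

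The antigens used for purification were compared in every group. SIRPA (chromosome 20, 1894167 to 1940592) rose from 113 ± 21.8 in iPSC to 999 ± 0.673 in switch-purified and 939 ± 17.5 in antibody-purified cells (adjusted p of 2.59e-06 and 3e-06). SIRPB1 had at most 8 reads in any library and was not tested. THY1 (chromosome 11, 119417378 to 119424985) fell from 2315 ± 140.5 to 47.9 ± 20.9 and 33.2 ± 1.61, ITGA1 from 234 ± 1.34 to 55.1 ± 10.6 and 49.1 ± 6.25, and PDGFRB from 149 ± 9.06 to 15.7 ± 1.17 and 21.4 ± 6.89. PECAM1 rose from 2.40 ± 2.03 to 37.1 ± 27.6 and 26.6 ± 7.66 (adjusted p of 0.00316 and 0.00477, but 0.0551 and 0.0718 without iPSC library 2). CD4 was at 39.5 ± 0.233 in iPSC, 29.2 ± 17.8 in switch-purified and 19.8 ± 0.546 in antibody-purified cells (adjusted p of 0.284 and 0.0893 against iPSC), and its count does not tell cellular from transfected CD4 mRNA. It would be called lower than in iPSC in switch-purified cells without the switch-purified library whose number matches no title (0.0256). In antibody-purified cells it would be called lower without switch_0605 (0.0216), without the other switch-purified library (0.0257) or in a fit of only these groups (0.0229). As a list the 6 tested antigens were not called, at adjusted p of 0.578 for switch-purified and 0.506 for antibody-purified cells against iPSC and 0.312 between the methods, and 6 of 6 did not pass between the methods.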

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

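The edgeR test with a replicate block and the limma block tests in 6 libraries or with a filter at 100 were added after seeing the data. A minimum log2 fold change of 1 gave 9636 and 9514 genes against iPSC and an overlap of 9021, since it leaves out small changes. Under the other alternatives the gene counts stayed within 1.5 times, and without single libraries they ran from 12166 to 14886 and from 11843 to 14571. Upper-quartile rescaling moved the median of all genes by -0.10 and -0.11 (log2). Between the methods DESeq2 called 28 genes, and leaving out single libraries gave 0 to 41. Where this left a group with 1 library, it was assumed to vary like the others. The titles share numbers but do not say that these mark a batch, and only 2 pairs exist, so the libraries were not paired. Deviations of the libraries with the shared number from their group means correlated at 0.297 across genes, and at 0.516 across those with a mean of at least 100. With a replicate block limma called 0 genes and 7 lists (adding stress, nodal, hypoxia, interferon and cholesterol), or 9 and 5 in all 6 libraries, 0 genes with the filter, and edgeR 342, 28 higher and 314 lower, with 10 of 11 endoderm genes lower. Camera with an estimated correlation called 0 lists in each comparison, and fry 21 and 21 against iPSC and 0 between the methods. The estimated correlation of pluripotency genes, -0.00165, was below the preset of 0.01, and yet they were not called with it. This count of 0 reflects the few residual degrees of freedom too, and does not show that correlation between genes accounts for the lost calls. The endoderm list had adjusted p of 5.89e-15 to 0.00117 without single libraries, 0.68 with an estimated correlation and 0.553 by fry, and the ATF4 list 0.00944 to 0.516, 0.68 and 0.553. Proliferation genes were called higher without switch_0605 (0.0335, range without single libraries 6.33e-07 to 0.691) and stress genes without the other switch-purified library (0.0233, range 7.61e-09 to 0.741), against their direction with all libraries. Apart from the fold minimum, the cause was not tested.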

Other observations

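Shares within 8 pairs of related genes, chosen after their values were seen, were not tested. MYH7 made up 3.68 ± 1.502% (SD, 2 libraries) of MYH6 and MYH7 together in switch-purified and 3.66 ± 1.70% in antibody-purified cells. The share was 4.74% in switch_0605 and 4.87% in SIRPA_0605, against 2.62% and 2.46% in the other library of each group. TNNI3, the troponin I of adult heart, made up 3.97 ± 0.425% and 3.77 ± 0.365% of TNNI1 and TNNI3 together, against 93.4 ± 0.693% in iPSC. A high share in these counts therefore does not by itself mark mature cardiomyocytes. MYL2, the ventricular light chain, made up 0.611 ± 0.184% and 0.567 ± 0.239% of MYL2 and MYL7 together. CKM made up 94.2 ± 0.527% and 93.3 ± 1.60% of CKM and CKB together, against 0.357 ± 0.0628% in iPSC. ATP2A2 made up 99.85 ± 0.000925% and 99.87 ± 0.0297% of ATP2A1 and ATP2A2, SLC2A4 36.6 ± 5.21% and 33.6 ± 6.26% of SLC2A1 and SLC2A4, and LDHB 70.4 ± 4.19% and 70.3 ± 4.08% of LDHA and LDHB. PKP2 made up 99.85 ± 0.0781% and 98.69 ± 1.16% of PKP2 and PKP3 together in switch- and antibody-purified cells.

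The epithelial list was added after the data were examined and holds CLDN6, named above, so it is not independent of the genes named there. With no minimum difference, all 15 of its genes were lower in switch_0605 than in SIRPA_0605 and in the other switch-purified library than in SIRPA_0619, with median log2 differences of -0.36 and -1.49, but ELF3 was equal in the first case apart from a log2 difference of -0.000215. For 11 of them the unadjusted p of limma was under 0.05, and for 0 the adjusted p. DESeq2 called 3 of the 15 lower, namely CLDN6 (adjusted p = 0.0256), GRHL2 (0.0119) and PRSS8 (0.0496). KRT8, singled out after its values were seen, was at 8061 and 9015 in switch-purified and 9557 and 10126 in antibody-purified libraries. In iPSC 14 of the genes had a mean of at least 100.

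Of the tests in the following paragraphs, those on scaling, leftover iPSC, a shared condition and depth were chosen after the result was seen. The endoderm and hepatic list was lower in switch-purified than in antibody-purified cells at camera's preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.68) or by fry (0.553), and 0 of its 11 members passed limma over all genes. A scaling difference would move all genes alike, but the list's median lay at -2.21 relative to that of all tested genes, with an upper quartile of -2.14, and undifferentiated iPSC cannot supply these transcripts, since 0 of the 11 genes had a higher mean in iPSC than in antibody-purified cells. RNA of endoderm-derived cells, which the sort would remove only where they lack SIRPA and SIRPB1 or carry an excluded antigen, may contribute. The median log2 difference of the second endoderm list (16 tested genes, 2 with a mean of at least 100 in iPSC and 0 in another list) was -1.47 between the group means, -0.71 between switch_0605 and SIRPA_0605, where it lay between the bounds of -1 and -0.5 set beforehand, and -1.77 between the remaining libraries, which no label pairs. Such RNA and a difference between the cardiomyocytes themselves cannot be told apart for these genes. The same holds for effects of transfection or puromycin, which only switch-purified cells received.

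Of 18 immediate early and dissociation stress genes 15 were higher in SIRPA_0605 and switch_0605 than in the other library of each group. HSPA1A, singled out after its values were seen, was at 5139 against 922 and 4688 against 803. Depth does not account for this, since these libraries had 0.967 times the reads of the others. Their deviations from the group means correlated at 0.504, over genes outside the list with a mean of at least 100. With 2 libraries per group each deviation rests on a single difference. Genes that vary together can give such a correlation without a shared condition, so it does not decide whether these libraries shared one. No biological explanation was tested, since no group follows these numbers.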
